A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

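RNA was measured in cultures of one haploid MATa laboratory strain of the budding yeast Saccharomyces cerevisiae. Per the labels' protocols, cells grew in synthetic complete medium at pH 4, 30 °C and 200 rpm. A preculture of 10 mL was kept for 24 h and diluted to an optical density of 0.05 in 50 mL. Cultures received 0 or 50 mM metformin, a biguanide drug used against type 2 diabetes, and were taken in the exponential or the stationary phase. RNA was depleted of ribosomal RNA and made into directional libraries, per the labels' protocols. The 14 libraries form 4 groups: exponential without metformin (n = 4), exponential with metformin (n = 4), stationary without metformin (n = 3) and stationary with metformin (n = 3). The labels give the same batch for all libraries. Nothing in them says whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The titles number the stationary replicates 1, 2 and 3, while the columns of the table number them 1, 2 and 5. The exponential columns are numbered 1 to 4, as in the titles. The titles' numbers were used, so nothing in the labels says that number 3 marks the same culture in both phases.

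The deposited table holds raw counts per feature, and reads were aligned with STAR and counted with HTSeq, with SAMtools also named, per the submitters' processing notes. Versions, genome build, annotation and the strand setting of the counting are not given in the sources used here. All 6470 feature identifiers matched the locus tags of the R64 reference annotation, which was used for names and feature types. Its coordinates were used to assign Ty genes to complete elements and families. The 5 summary rows of HTSeq were kept out of library sizes and tests. They held 9.33% ± 0.323 (SD, n = 4) of all reads counted in exponential libraries without metformin, 9.56% ± 0.378 (n = 4) with metformin, 6.99% ± 0.659 (n = 3) in stationary libraries without and 6.32% ± 0.175 (n = 3) with metformin. Reads with more than a single best alignment made up 6.44% ± 0.305 (SD, n = 4) in exponential and 1.25% ± 0.140 (n = 3) in stationary libraries without metformin. Reads that overlapped several features made up 0.424% ± 0.00588 (n = 4) and 1.98% ± 0.0348 (n = 3). Reads of these kinds are lost for genes with near-identical copies, such as retrotransposons and paralogs, and for overlapping genes, whose values are therefore uncertain.

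Gene counts summed to 43897221 to 59443572 per library. Features with too few reads were removed with filterByExpr (minimum count 10, minimum total 15), which left 6097 features. Counts were scaled with TMM and fitted with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, all libraries in the same fit with group as the term and no replicate block. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation per group lay between 13.5% and 17.2%. Standard errors of log2 fold changes were derived from the test statistic. Levels are CPM, counts scaled to a common library size with TMM. No libraries of a group agreed within sampling noise.

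The comparisons were metformin against none in each phase, stationary against exponential cultures without and with metformin, and the difference of the metformin effect between phases. Before the data were examined, 36 gene lists were fixed and tested with camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry. Counts of the genes of complete Ty elements were summed per family (Ty1 60, Ty2 20, Ty3 3 and Ty4 4 genes) and tested in the same model, adjusted over the families, with an exact permutation test on CPM. The rule for named genes was fixed at the same time. It took the 8 largest rises and 8 largest falls with adjusted p under 0.05, a mean of at least 10 CPM in a group and no overlap between groups, leaving out engineered loci and non-coding RNA. For the phase comparison with metformin it took 4 of each, and for the interaction 6 of each. For each list that passed in the first 3 comparisons it added the 2 members with the lowest p in the list's direction and 1 in the other direction if it passed, and it added the engineered loci, the Ty families and the 2 Ty genes with the lowest p. Genes named outside this rule are said to be so. In the simulated recovery test, counts were drawn with 200 genes changed. For metformin in exponential cultures, 70.1% of genes changed 1.5-fold and 89.6% of those changed 2-fold were recovered among 6067 genes, with 12 false calls among 183. For metformin in stationary cultures these shares were 52.2% and 82.1%, with 8 false calls among 162. For stationary against exponential cultures they were 70.1% and 89.6% without metformin and 64.2% and 85.1% with metformin, among 6012 genes. The counts for the phases were drawn from the exponential means in both phases. The real phases differed in most genes, so these shares do not describe the real phase comparisons. For the interaction the shares recovered were 20.0% and 80.0% among 6067 genes. All draws were independent between genes, without the deviations that real libraries share across genes, described below. With 200 changed genes the adjustment is also milder than with few. The shares for metformin and the interaction therefore do not give the power of the real comparisons.

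Replicate numbers recur across groups. Deviations of same-numbered libraries from their group means correlated across genes at 0.302, 0.103, 0.624 and 0.232 between the exponential groups and at 0.259, 0.136 and 0.467 between the stationary groups. They correlated at 0.151, 0.261 and 0.216 between the phases with metformin. All these exceeded 0.1, a limit that no test was used to set, so the libraries were treated there as possibly paired. The main fit has no replicate block, which was run as an alternative. Between the phases, number 3 sets the exponential column 3 against the stationary column 5. The pairing is uncertain, since the exponential library numbered 2 and the stationary library numbered 1 without metformin correlated better with a differently numbered library. Between the phases without metformin the correlations were -0.0330, -0.0592 and -0.0516, and the numbers do not pair the libraries. Alternatives were RLE scaling, scaling by nuclear protein-coding genes, other filters, the replicate block, glmTreat against 1.5-fold, limma-voom, DESeq2 1.42.0, a fit of the compared groups alone and the omission of each library in turn.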

Results

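Transcripts of yeast cultures were counted in the exponential and stationary phases, each with and without 50 mM metformin, in 14 libraries of 43897221 to 59443572 gene counts. The series title places the study in the field of retrotransposon activity, metformin and chronological aging, which is the survival of non-dividing cells in stationary culture. The first principal component held 91.8% of the variance and separated the phases. The exponential library with metformin numbered 3 lay furthest out on the second component, at 28.4 against -15.2 to 13.9 for the other 13 libraries.

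The loci altered in the strain were read first. URA3, the uracil synthesis gene deleted in the strain, had 0 counts in all 14 libraries, which allows up to 3 counts in each. HIS3, a histidine synthesis gene that is also deleted, had 0 to 18 counts per library. LYP1, the lysine permease, had 0 to 8 counts in exponential and 26 to 50 in stationary libraries. CAN1, the arginine permease that the genotype label gives as replaced, had 1334 to 1877 counts in exponential and 67 to 106 in stationary libraries. Its reads go against the label in every library, so CAN1 is given here as a count and not as a checked deletion. LEU2, a leucine synthesis gene present in the strain, stood at 30.1 ± 0.852 CPM (SD, n = 4) in exponential cultures without metformin. PDC1, the main pyruvate decarboxylase and the gene tagged with a fluorescent protein, stood at 4015 ± 987 CPM (SD, n = 4) in the same group. Tests of deletions by reads outside the removed part would check nothing, and the removed intervals are not given in the sources used here.

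Metformin in exponential cultures was followed by higher transcripts of iron uptake genes. FIT2, a cell wall mannoprotein that retains siderophore-bound iron, rose from 16.0 ± 2.42 to 52.2 ± 11.0 CPM (SD, n = 4 each), a log2 fold change of 1.71 (SE 0.21, adjusted p = 0.00503). Its relative FIT3 rose from 19.3 ± 3.76 to 57.0 ± 12.5 CPM (n = 4 each), by 1.56 (SE 0.25, adjusted p = 0.0289). ARN2, a siderophore transporter, rose by 0.92 (SE 0.13, adjusted p = 0.0151), and FRE2, a ferric reductase, rose by 0.82 (SE 0.10, adjusted p = 0.00447). FRE5, a putative ferric reductase named after its values were seen, rose by 1.57 (SE 0.24, adjusted p = 0.0221). ADY2, an acetate transporter, rose from 0.709 to 1.40 CPM, by 0.98 (SE 0.17, adjusted p = 0.0455).

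These 6 genes were all that passed among 6097 in the edgeR test, and 0 genes fell. At an unadjusted p under 0.05 there were 108 genes, 90 of them higher, where 305 would be called with no change. DESeq2 called 8 genes and limma-voom 4. With the replicate block 4 genes passed, and FIT3 (adjusted p = 0.0821) and ADY2 (adjusted p = 0.545) did not. Leaving out exp_control 1 or 2, or exp_metformin 1, 2 or 4, left 2 genes, FIT2 and FRE2, and leaving out exp_control 3 left 3. No gene passed a test against a 1.5-fold change.

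The iron regulon, the genes switched on by the regulators Aft1 and Aft2 when iron is short, was higher as a list. Of its 30 tested members 27 had a positive log2 fold change, with a median of 0.29, and 5 rose over all genes tested, against 12 when adjusted over the list alone. Camera gave an adjusted p of 1.24e-46, and the adjusted p = 0.0189 with an estimated correlation. Fry gave an adjusted p of 0.110. In the interaction test the list stood at a median of -0.25, with camera adjusted p = 6.34e-12 and adjusted p = 0.382 with an estimated correlation.

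**Figure D1:**
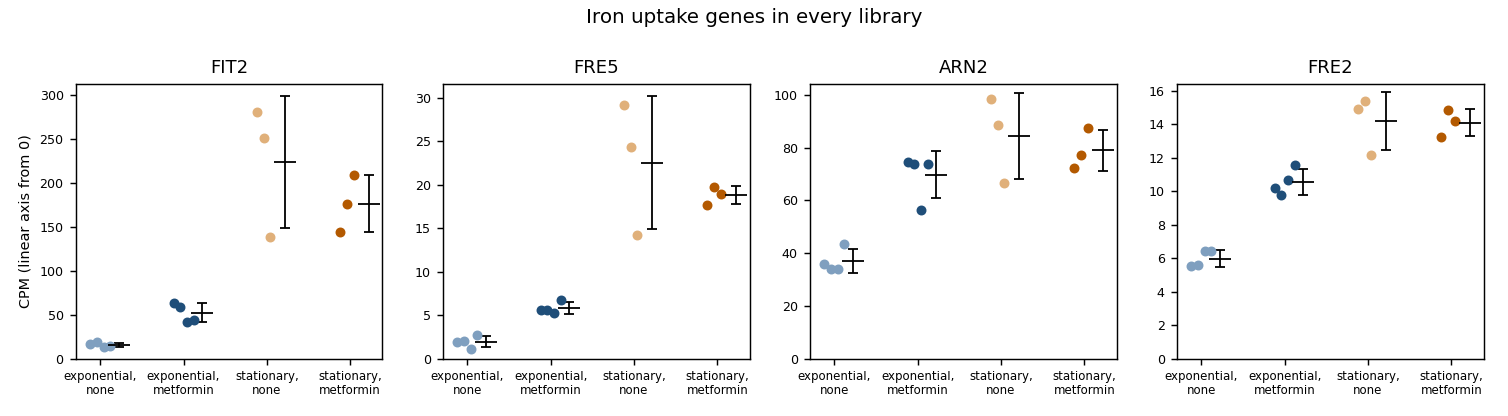
CPM of 4 iron uptake genes in each library (points), with the group mean and SD (black, n = 4 exponential and n = 3 stationary), on linear axes from 0. FIT2 stood at 16.0 CPM in exponential cultures without metformin, 52.2 with it, and 224.1 and 176.8 in stationary cultures without and with it.

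The other lists that passed camera in exponential cultures held 1 called gene, ADY2, and lost their call with an estimated correlation. Hexose transporters had 15 of 18 members positive, with a median of 0.30 and adjusted p = 0.278 with an estimated correlation. HXT10, a minor member, stood at 0.373 ± 0.138 and 0.882 ± 0.606 CPM (n = 4 each), with 1.77 CPM in exp_metformin 3 against 0.421 to 0.705 in the other libraries with metformin. Gluconeogenesis, glyoxylate cycle and acetate use genes had a median of 0.12, with 1 called gene over all genes and 1 adjusted over the list alone (adjusted p = 0.741 with an estimated correlation). Meiosis and sporulation genes (median 0.15, adjusted p = 0.740 with an estimated correlation), cell wall mannoproteins of anaerobic growth (median 0.12, adjusted p = 0.740 with an estimated correlation) and Ty genes (38 of 44 positive, median 0.15, adjusted p = 0.741 with an estimated correlation) held 0 called genes over all genes and 0 adjusted over the list alone. The high value of SPS2, a sporulation gene, rested on the same library, which held 0.546 CPM against 0.0421 to 0.0961 in the other exponential libraries with metformin. Leaving out a library ended several of these calls by camera. Ty genes had a median of 0.04 without exp_metformin 4 (adjusted p = 0.0604), and hexose transporters 0.24 without exp_control 3 (0.252). Gluconeogenesis genes had -0.02 without exp_control 3 (0.773) and 0.02 without exp_metformin 1 (0.229). Meiosis genes had 0.07 without exp_control 3 (0.202) and 0.04 without exp_metformin 3 (0.0773), and the mannoproteins 0.12 (0.183) and 0.07 (0.240) without the same libraries.

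Lower lists were small in size. Mitochondrial ribosomal proteins had 1 of 56 members positive and a median of -0.08 (adjusted p = 0.381 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes, among them the cytochrome c gene CYC1 at -0.24 (SE 0.10), had a median of -0.11 (adjusted p = 0.741 with an estimated correlation). Cytosolic ribosomal proteins (median -0.06), heat shock chaperones (median -0.11) and the proteasome (median -0.03) each had adjusted p = 0.741 with an estimated correlation. Mating genes of MATa cells, such as the agglutinin subunit AGA2 at -0.30 (SE 0.10) and the pheromone gene MFA1 at -0.33 (SE 0.15), had a median of -0.04 and adjusted p = 0.0662 with an estimated correlation. In these 6 lists 0 genes fell over all genes tested and 0 adjusted over the list alone. By camera the chaperones had a median of 0.04 without exp_control 1 (adjusted p = 0.395), -0.03 without exp_control 2 (0.158), -0.08 without exp_metformin 2 (0.0999), -0.03 without exp_metformin 3 (0.906) and -0.05 without exp_metformin 4 (0.684). The proteasome had -0.04 without exp_control 1 (0.0630), -0.01 without exp_control 3 (0.525), and -0.02 without exp_metformin 2 (0.155) or 4 (0.485). Cytosolic ribosomal proteins had -0.03 without exp_metformin 3 (0.0904).

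In stationary cultures 3 genes rose with metformin, of which TRR1 and GPX2 act against peroxides. TRR1, the cytosolic thioredoxin reductase, rose from 36.5 ± 2.58 to 75.6 ± 13.4 CPM (SD, n = 3 each), a log2 fold change of 1.05 (SE 0.12, adjusted p = 0.00213). GPX2, a glutathione peroxidase, rose from 12.2 ± 3.53 to 31.0 ± 8.31 CPM (n = 3 each), by 1.34 (SE 0.21, adjusted p = 0.0355). YLR108C, a gene of unknown function, rose from 27.7 ± 0.340 to 47.2 ± 5.10 CPM (n = 3 each), by 0.77 (SE 0.11, adjusted p = 0.0206). The paralogs TRR2 (-0.04, SE 0.11), GPX1 (-0.32, SE 0.38) and HYR1 (-0.08, SE 0.12), named after their values were seen, did not pass.

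These 3 genes were all that passed among 6097 in the edgeR test, and 0 fell. At an unadjusted p under 0.05 there were 490 genes, 340 of them higher, where 305 would be called with no change. With the replicate block 10 genes passed, 9 higher and 1 lower: these 3, SSA2, INO1, CIP1, MPC2, ISU2, CTS1 and AAC3. SSA2, a cytosolic Hsp70 chaperone, had 0.83 with an adjusted p of 0.0438 in that fit, and at 0.79 with 0.200 without the block. DESeq2 called 47 genes (35 higher), limma-voom 7, and the fit of these 2 groups alone 0. Leaving out stat_control 1 or 2, or stat_metformin 1 or 3, left TRR1 alone, while 13 genes passed without stat_control 3 and 8 without stat_metformin 2.

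**Figure D2:**
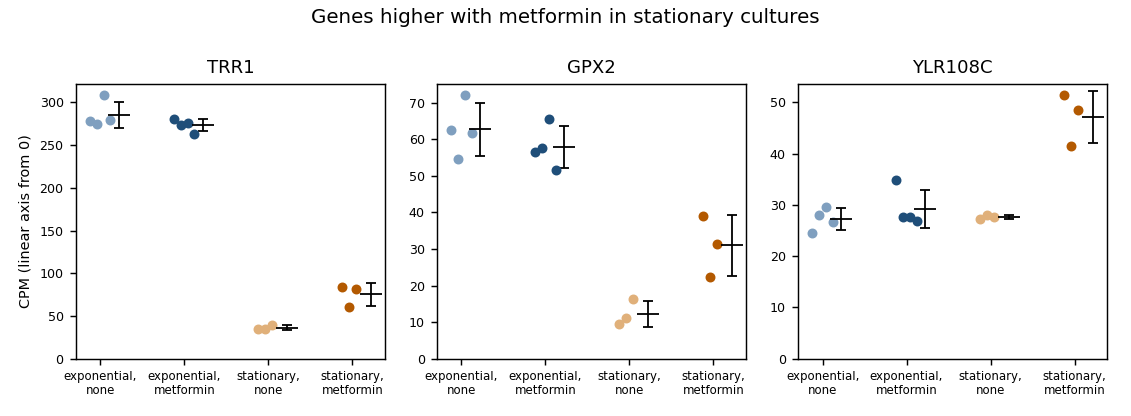
CPM of TRR1, GPX2 and YLR108C in each library (points), with the group mean and SD (black, n = 4 exponential and n = 3 stationary), on linear axes from 0. TRR1 stood at 285.2 and 273.2 CPM in exponential cultures without and with metformin, and at 36.5 and 75.6 in stationary cultures.

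The oxidative stress defence list, which holds TRR1 and GPX2, had 22 of 29 members positive with a median of 0.18. It had 2 genes that rose over all genes tested and 5 adjusted over the list alone (camera adjusted p = 5.35e-09, adjusted p = 0.628 with an estimated correlation). SRX1, the sulfiredoxin that repairs oxidised peroxiredoxins, stood at 1.28 (SE 0.25, adjusted p = 0.0921) and was named after its values were seen. Heat shock chaperones had 22 of 23 members positive and a median of 0.34, with 0 called genes and 1 adjusted over the list alone (adjusted p = 0.718 with an estimated correlation). SSA1, a further Hsp70 gene, stood at 0.71 (SE 0.25, adjusted p = 0.406).

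Some lists of respiratory metabolism were also higher by camera in stationary cultures with metformin, with 0 called genes over all genes tested, and each had adjusted p = 0.718 with an estimated correlation. Nuclear-encoded oxidative phosphorylation was not, with 13 of 40 members positive and a median of -0.05 (camera adjusted p = 0.172). Gluconeogenesis, glyoxylate cycle and acetate use genes had 18 of 19 members positive and a median of 0.26 (adjusted p = 0.718 with an estimated correlation), and ADY2 stood at 0.82 (SE 0.16, adjusted p = 0.0921). The 6 mitochondrially encoded genes of oxidative phosphorylation were all positive with a median of 0.31 (adjusted p = 0.718 with an estimated correlation), COX1 at 0.31 (SE 0.13) and COX3 at 0.34 (SE 0.16). Tricarboxylic acid cycle genes had a median of 0.16 (adjusted p = 0.718 with an estimated correlation), with LSC2, a succinyl-CoA ligase subunit, at 0.37 (SE 0.09). Peroxisomal fatty acid oxidation had a median of 0.11 (adjusted p = 0.718 with an estimated correlation). Adjusted over each of these 4 lists alone, 1 gene passed in the first, 0 in the second, 1 in the third and 0 in the fourth. Retrograde response genes (9 of 10 positive, median 0.24, 0 adjusted over the list alone) and histones (8 of 11 positive, median 0.15, 2 adjusted over the list alone) had adjusted p = 0.718 with an estimated correlation as well. Leaving out a library ended calls by camera here too. Gluconeogenesis genes had a median of 0.09 (adjusted p = 0.457) and retrograde genes 0.17 (0.0816) without stat_control 3. The mitochondrially encoded genes had 0.23 without stat_control 1 (0.783), 0.31 without stat_metformin 1 (0.0678) and 0.23 without stat_metformin 3 (0.278). Tricarboxylic acid cycle genes had 0.12 without stat_control 1 (0.100) and 0.08 without stat_metformin 3 (0.115). Peroxisomal genes had 0.13 (0.0508), 0.06 (0.100) and 0.01 (0.468) without stat_control 1, stat_control 2 and stat_metformin 3. Histones had 0.14 (0.205), 0.17 (0.0658), 0.13 (0.0932) and 0.08 (0.165) without stat_control 2, stat_control 3, stat_metformin 1 and stat_metformin 3.

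The 3 lower lists in stationary cultures with metformin were cytosolic ribosomal proteins, ribosome biogenesis, and meiosis and sporulation. Cytosolic ribosomal proteins had 6 of 137 members positive and a median of -0.11 (adjusted p = 0.899 with an estimated correlation), and ribosome biogenesis had 4 of 73 positive and a median of -0.09 (adjusted p = 0.947 with an estimated correlation). NOP16, a nucleolar factor of the large subunit, stood at -0.58 (SE 0.21). Meiosis and sporulation genes had a median of -0.19 (adjusted p = 0.718 with an estimated correlation). In these 3 lists 0 genes passed over all genes and 0 adjusted over the list alone. By camera the cytosolic ribosomal proteins had a median of 0.02 without stat_control 3 (adjusted p = 0.961), and ribosome biogenesis -0.02 without stat_control 1 (0.212) or stat_metformin 3 (0.274). Meiosis genes had -0.16 (0.205), -0.10 (0.0954), -0.14 (0.0932) and -0.10 (0.502) without stat_control 2, stat_control 3, stat_metformin 1 and stat_metformin 2. The share of reads outside any feature was 3.75% ± 0.492 (SD, n = 3) without and 3.03% ± 0.117 (n = 3) with metformin, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows.

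Retrotransposons are the subject named in the title, and their families were compared as sums over complete elements. In stationary cultures Ty1 stood at 1865 ± 316 CPM without and 2522 ± 572 CPM with metformin (SD, n = 3 each, exact permutation p = 0.2). Its log2 fold change was 0.44 (SE 0.18, adjusted p = 0.0590 over the families). Ty2 stood at 0.33 (SE 0.13, adjusted p = 0.0590), Ty4 at 0.23 (SE 0.10, adjusted p = 0.0596) and Ty3 at 0.18 (SE 0.16, adjusted p = 0.266), so 0 families passed in the edgeR test. With the replicate block 3 families passed, Ty1 at 0.42 (adjusted p = 0.0190), Ty2 at 0.32 (adjusted p = 0.0169) and Ty4 at 0.22 (adjusted p = 0.0427). DESeq2 gave 2 families, as did the fits without stat_control 3 or without stat_metformin 2. As a list, 44 of 44 tested Ty genes were positive with a median of 0.41, 0 called over all genes and 5 adjusted over the list alone. The other Ty genes of the 89 listed had too few reads to be tested. Ty copies share reads and the same libraries, so the 44 genes are not separate measurements. Camera gave an adjusted p of 2.57e-19, and the adjusted p = 0.628 with an estimated correlation. The Ty1 gene YDR098C-B stood at 0.57 (SE 0.16, adjusted p = 0.251) and YDR261C-D at 0.44 (SE 0.12, adjusted p = 0.249).

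In exponential cultures 0 Ty families passed with metformin in edgeR, and 0 in DESeq2, with unadjusted p from 0.0849 to 0.964 in edgeR. Ty1 stood at 0.14 (SE 0.16, adjusted p = 0.550) and Ty2 at 0.21 (SE 0.11, adjusted p = 0.340). Without exp_metformin 4 the value of Ty1 was -0.02. The difference of the metformin effect between the phases was 0.30 (SE 0.24, adjusted p = 0.461) for Ty1 and did not pass for any of the 4 families.

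All 4 families rose from the exponential to the stationary phase. Without metformin Ty1 rose from 649.3 ± 25.4 (SD, n = 4) to 1865 ± 316 CPM (n = 3), by 1.52 (SE 0.17, adjusted p = 6.94e-07, exact permutation p = 0.0286). Ty3 rose by 1.51 (SE 0.15, adjusted p = 3.83e-07), Ty2 by 0.59 (SE 0.12, adjusted p = 0.000266) and Ty4 by 0.47 (SE 0.09, adjusted p = 0.000266). With metformin Ty1 rose by 1.82 (SE 0.17), Ty3 by 1.58 (SE 0.15), Ty2 by 0.71 (SE 0.12) and Ty4 by 0.70 (SE 0.09). Of 44 tested Ty genes 40 rose and 1 fell without metformin, over all genes and adjusted over the list alone (camera adjusted p = 0.000473, adjusted p = 0.610 with an estimated correlation). YNL284C-B rose by 2.78 (SE 0.18) and YDR098C-B by 2.11 (SE 0.15). The gene that fell, YDR170W-A at -0.64 (SE 0.13), belongs to a mutant element and to no family sum. Reads that HTSeq set aside as not unique were fewer in stationary libraries (1.25% against 6.44%), and Ty copies share reads. As plain shares of gene counts, without metformin, Ty genes held 0.116% ± 0.00202 (SD, n = 4) in exponential libraries. In stationary libraries they held 0.146% ± 0.0207 (n = 3). The size of the rises of the families therefore depends on the TMM scaling. As a plain share Ty genes as a whole were also higher in stationary libraries, with an exact permutation p of 0.0286 without metformin and 0.0571 with it. Plain shares of single families were not compared.

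**Figure D3:**
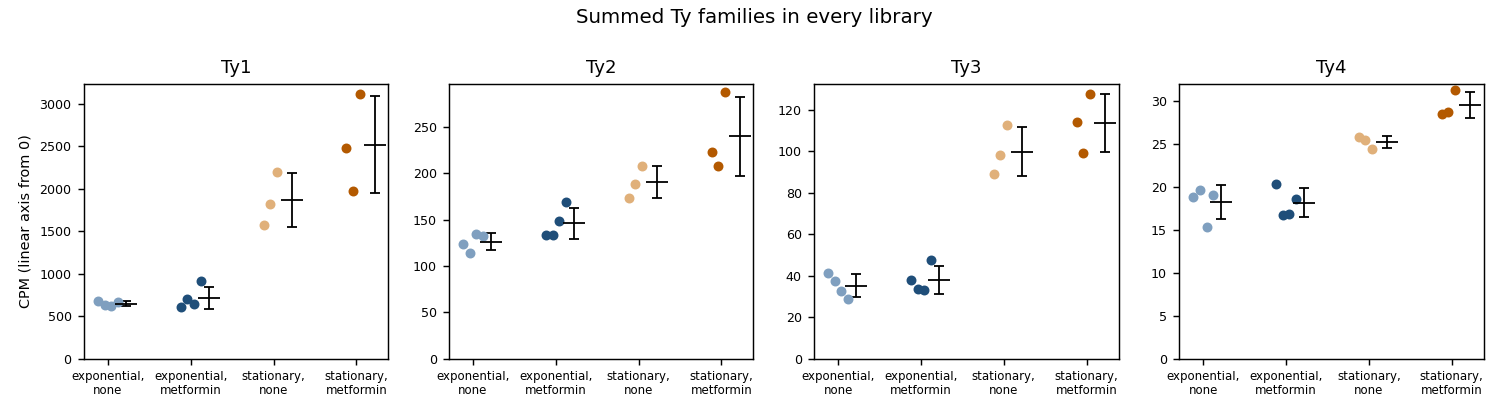
Summed CPM of the genes of each Ty family in each library (points), with the group mean and SD (black, n = 4 exponential and n = 3 stationary), on linear axes from 0. Ty1 stood at 649.3, 714.6, 1865 and 2522 CPM from left to right.

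The change of phase without metformin reached most of the transcriptome. Of 6097 genes 2585 rose and 2574 fell, 84.6% in all, and 3094 changed at least 2-fold. The largest rises were in SIP18 (log2 fold change 10.93, SE 0.49), a hydrophilin of desiccation tolerance, DPA10 (10.61, SE 0.34), GRE1 (10.46, SE 0.55), a related hydrophilin, and ADY2 (10.30, SE 0.21). They continued with YPL276W (9.41, SE 0.41) and FDH2 (9.14, SE 0.38), of the formate dehydrogenase family, whose near-identical copies make their counts uncertain. SPG1 (8.98, SE 0.71), a gene needed for survival in stationary phase, and RGI2 (8.98, SE 0.55), a gene of energy metabolism, followed. The largest falls were in PDC5 (-7.64, SE 0.27), a pyruvate decarboxylase, ENO2 (-7.06, SE 0.22), an enolase, and SSA2 (-6.85, SE 0.25). They continued with YHB1 (-6.67, SE 0.20), a nitric oxide dioxygenase, UTR2 (-6.52, SE 0.21), a cell wall transglycosylase, and LYS9 (-6.42, SE 0.13) of lysine synthesis. IMD2 (-6.04, SE 0.29), an enzyme of GTP synthesis, and MRH1 (-5.97, SE 0.14), a plasma membrane protein, completed them. Adjusted p lay between 1.32e-13 and 2.16e-08 for these 16 genes. Several of them (PDC5, ENO2, SSA2, IMD2) have close paralogs.

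Most glycolysis genes were lower in the stationary phase, and most genes of acetate use, fatty acid oxidation and oxidative phosphorylation were higher. The tricarboxylic acid cycle list went both ways, with 7 of 17 genes that rose and 8 that fell, also adjusted over the list alone (camera adjusted p = 0.751). All 19 genes of gluconeogenesis, the glyoxylate cycle and acetate use rose, with a median of 5.55 and YAT1, a carnitine acetyltransferase, at 6.22 (SE 0.17). Their camera adjusted p was 9.57e-13, and adjusted p = 0.237 with an estimated correlation. Peroxisomal fatty acid oxidation had 16 of 17 members that rose, POX1, the acyl-CoA oxidase, by 8.59 (SE 0.19) and CTA1, the peroxisomal catalase, by 7.48 (SE 0.17), while ANT1, an adenine nucleotide carrier, fell by 2.58 (SE 0.08); adjusted p = 0.117 with an estimated correlation. In glycolysis and fermentation 16 of 21 fell and 3 rose, with a median of -2.90, and PDC6, a minor pyruvate decarboxylase, rose by 6.34 (SE 0.29); adjusted p = 0.237 with an estimated correlation. All 6 mitochondrially encoded genes rose, COX1 by 5.36 (SE 0.13) and COX3 by 4.82 (SE 0.17), subunits of cytochrome c oxidase; adjusted p = 0.237 with an estimated correlation. Nuclear-encoded oxidative phosphorylation had 26 of 40 that rose and 6 that fell, NDE2, an external NADH dehydrogenase, by 5.99 (SE 0.33) and SDH2 by 2.89 (SE 0.17), while SDH3 fell by 1.71 (SE 0.12); adjusted p = 0.737 with an estimated correlation.

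Cytosolic ribosomal proteins and the lists of amino acid and ergosterol synthesis, the proteasome, histones and the cell cycle were lower in the stationary phase. Ribosome biogenesis did not pass camera, with 41 of 73 genes that fell and 11 that rose, the same adjusted over the list alone (adjusted p = 0.257). Of 137 cytosolic ribosomal proteins 135 fell, with a median of -2.99, RPL9A at -4.82 (SE 0.13) and RPS18B at -3.97 (SE 0.11); camera gave 1.97e-31, and adjusted p = 0.237 with an estimated correlation. Of 54 amino acid biosynthesis genes 46 fell and 4 rose, ARO8, an aromatic aminotransferase, at -3.87 (SE 0.11) and BAT2, a branched-chain aminotransferase, at 2.51 (SE 0.08); adjusted p = 0.237 with an estimated correlation. Ergosterol genes had 24 of 25 that fell, ERG6 at -4.71 (SE 0.12) and ERG10 at -2.97 (SE 0.08), while UPC2, the regulator of sterol genes, rose by 1.32 (SE 0.12); adjusted p = 0.117 with an estimated correlation. Of 33 proteasome genes 32 fell, PRE9 at -2.07 (SE 0.07) and RPT5 at -1.90 (SE 0.07), while RPN4, their transcription factor, rose by 1.66 (SE 0.16); adjusted p = 0.381 with an estimated correlation. Of 11 histone genes 10 fell, HTA2 at -4.20 (SE 0.12) and HTB2 at -2.74 (SE 0.09); adjusted p = 0.237 with an estimated correlation. Among cyclins and S phase genes 25 of 31 fell and 4 rose, the mitotic cyclin CLB1 at -3.67 (SE 0.16), the clamp POL30 at -2.93 (SE 0.15) and the S phase cyclin CLB5 at 1.24 (SE 0.15); adjusted p = 0.737 with an estimated correlation.

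The lists of the general stress response, autophagy, nitrogen catabolite repression, the iron regulon, and thiamine and vitamin B6 were higher by camera and lost their call with an estimated correlation, while heat shock chaperones, a list that did not pass (camera adjusted p = 0.202), had 16 of 23 members that fell and 2 that rose, also adjusted over the list alone. In the general stress response 20 of 30 rose and 3 fell, SSA3, an inducible Hsp70, by 3.61 (SE 0.10) and GND2 by 4.37 (SE 0.19), with GRE3, an aldose reductase, at -2.01 (SE 0.15); adjusted p = 0.737 with an estimated correlation. Of 23 autophagy genes 19 rose and 3 fell, with the mitophagy receptor ATG32 at 3.46 (SE 0.11), ATG11 at 3.04 (SE 0.08) and ATG19 at -1.05 (SE 0.13); adjusted p = 0.363 with an estimated correlation. Nitrogen catabolite repression targets had 16 of 28 that rose and 6 that fell, PUT4, the proline permease, at 6.26 (SE 0.20) and CAR2 of arginine breakdown at 5.53 (SE 0.15); adjusted p = 0.237 with an estimated correlation. Of 30 iron regulon genes 20 rose and 6 fell, ISU1, a scaffold of iron-sulfur clusters, at 2.91 (SE 0.09), BNA2 at 5.66 (SE 0.16) and FRE1, a ferric reductase, at -1.48 (SE 0.14); adjusted p = 0.608 with an estimated correlation. Thiamine and vitamin B6 genes had 16 of 22 that rose and 2 that fell, SNZ1 at 6.43 (SE 0.17), THI4 at 2.84 (SE 0.10) and the phosphatase PHO3 at -5.48 (SE 0.15); adjusted p = 0.237 with an estimated correlation.

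Among the remaining lists that passed, 37 of 56 mitochondrial ribosomal proteins rose and 12 fell, with MRPS17 at 2.02 (SE 0.12), MRPS5 at a 2.84-fold rise and MRPL32 at -2.43 (SE 0.12); adjusted p = 0.737 with an estimated correlation. Cell wall mannoproteins of anaerobic growth had 17 of 23 that rose and 2 that fell, PAU2 at 3.97 (SE 0.24), TIR4 at 1.89 (SE 0.12) and TIR3 at -2.40 (SE 0.18); adjusted p = 0.381 with an estimated correlation. Nutrient signalling and lifespan regulators had 17 of 32 that rose and 6 that fell, SIP2 at 2.36 (SE 0.10) and SNF4 at -1.36 (SE 0.09), both subunits of the Snf1 kinase, and SIR3, a silencing factor, at 1.92 (SE 0.08). That list had adjusted p = 0.381 with an estimated correlation, and camera gave 0.0423 and, with the replicate block, 0.0516. Without stat_control 1 it gave 0.0548, as it did for mitochondrial ribosomal proteins, and without stat_control 2 it gave 0.0541. Markers of other cell types were read as well. Of 31 meiosis and sporulation genes 25 rose and 3 fell, RIM4, a repressor of meiotic translation, at 5.56 (SE 0.13), SPO20 at 6.16 (SE 0.15) and SPO16 at -1.99 (SE 0.45); adjusted p = 0.237 with an estimated correlation. The 4 tested MATalpha genes all rose, with a camera adjusted p of 0.0987.

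**Figure D4:**
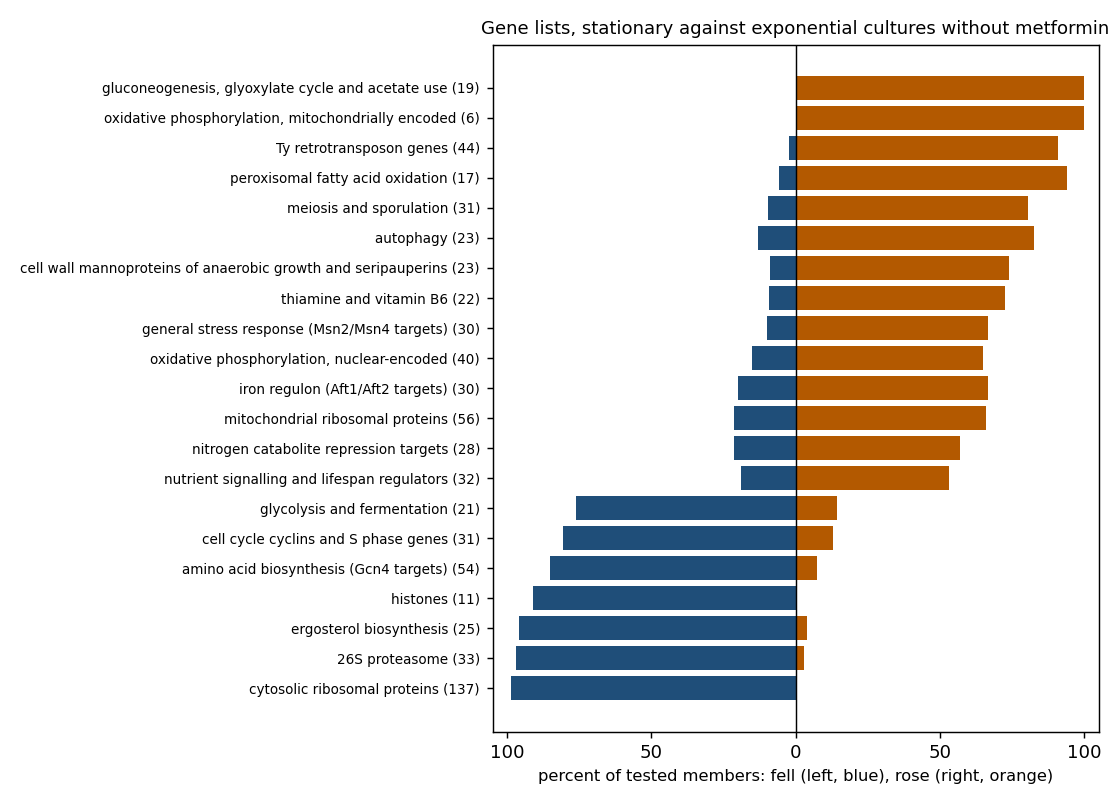
Share of the tested members of each gene list (number in brackets) that rose (right, orange) or fell (left, blue) in stationary against exponential cultures without metformin, in percent, for the 21 lists that passed camera. All 19 gluconeogenesis genes rose and 135 of 137 cytosolic ribosomal protein genes fell.

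In this comparison 21 of 36 lists passed camera, 14 higher and 7 lower, and their counts were the same adjusted over the list alone. With an estimated correlation 0 passed, and by fry, which does not compare a list with other genes, 31 passed. Library make-up differed between the phases beside all these groups: nuclear protein-coding genes took 84.6% ± 1.34 (SD, n = 4) of gene counts in exponential and 26.6% ± 2.88 (n = 3) in stationary libraries. Small nucleolar RNA took 5.32% ± 0.569 and 19.5% ± 0.884, spliceosomal RNA 1.90% ± 0.165 and 14.9% ± 0.471, and other non-coding RNA 7.35% ± 0.619 and 34.4% ± 1.66. Levels and fold changes are relative to the TMM scaling, so they give no amount of transcript per cell. The TMM factors were 1.35 to 1.52 in exponential and 0.492 to 0.744 in stationary libraries. Scaling by nuclear protein-coding genes alone gave 2700 genes that rose and 2482 that fell.

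The same comparison with metformin present gave 2490 genes that rose and 2546 that fell, 82.6% of those tested. The largest rises were in SIP18 (10.99, SE 0.49), GRE1 (10.71, SE 0.56), DPA10 (10.18, SE 0.34) and ADY2 (10.14, SE 0.21). The largest falls were in PDC5 (-7.60, SE 0.27), ENO2 (-6.82, SE 0.22), IMD2 (-6.47, SE 0.30) and UTR2 (-6.43, SE 0.21). Gene lists passed camera in 20 cases, 13 higher and 7 lower, and with an estimated correlation in 0, while 34 passed by fry. All 19 gluconeogenesis genes rose (median 5.71, 19 adjusted over the list alone, adjusted p = 0.200 with an estimated correlation). Of 137 cytosolic ribosomal proteins 135 fell (median -3.02, 135 adjusted over the list alone, adjusted p = 0.282 with an estimated correlation).

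Whether metformin acted differently in the phases was tested by the interaction. TRR1 had a larger metformin effect in stationary than in exponential cultures, by 1.11 on the log2 scale (SE 0.15, adjusted p = 0.0243), with 285.2 ± 15.5 and 273.2 ± 7.07 CPM (SD, n = 4 each) in exponential cultures without and with metformin. It was the single gene that passed in edgeR, and with the replicate block 0 passed (TRR1 adjusted p = 0.0542). At an unadjusted p under 0.05 there were 338 genes, where 305 would be called with no change. DESeq2 called 15 and limma-voom 1, TRR1. Leaving out a single library gave 16 genes without stat_control 3, 3 without exp_metformin 3, 2 without stat_metformin 2 and 1 (FIT3, not TRR1) without stat_metformin 3. Leaving out exp_control 1, 2, 3 or 4, exp_metformin 1, 2 or 4, stat_control 1 or 2, or stat_metformin 1 gave 0. FIT2 stood at -2.05 (adjusted p = 0.0567) and FRE5 at -1.83 (adjusted p = 0.137), both chosen after their values were seen.

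The genes called by edgeR in the metformin comparisons of the phases did not overlap, with 6 and 3 genes and 0 shared, where independent lists would share 0.00295, too few to show less overlap. ADY2, at 0.98 and 0.82, was called in both by DESeq2. Across genes, which are not independent replicates, the log2 fold changes correlated at -0.355 (Pearson) and -0.0477 (Spearman). The 6 genes that rose with metformin in exponential cultures all rose also from exponential to stationary phase without it. These comparisons share their exponential controls, which by itself makes genes overlap. A Fisher exact test across genes (p = 0.00579, with 2.54 shared by independent lists) therefore decides nothing about this overlap. The log2 fold changes of these comparisons correlated at 0.332 across genes, against 0.440 for simulated unchanged groups and 0.225 with the controls split (mean of 6 splits, 0.0322 to 0.392). The simulated groups had no phase change, while most real genes had. The simulated correlation is therefore no measure for the real correlation, and nothing is concluded from their order. The covariance was 0.109 against 0.0173 simulated, a difference of 0.0915, and 0.0142 to 0.156 over the splits of the controls.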

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

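In this part the splits, the test of the paralogs and the use of the planned fits without one library to weigh the rise of TRR1 and GPX2 were chosen after the results were seen. In 252 groups of 4 libraries the highest or lowest value was compared with the others, and in 18 its gap exceeded the limit, where chance alone would give 12.6. The numbers in brackets are the gap divided by the range of the group. Of the exponential libraries with metformin, the one numbered 3 was high in PDC5 (0.891), CYC1 (0.874), SPS2 (0.893), the share of reads outside features (0.889) and the share of transfer RNA (0.839), and low in ARN2 (0.955). The library numbered 1 was high in YLR108C (0.898) and GRE3 (0.915) and low in TIR4 (0.864). The library numbered 4 was low in ANT1 (0.949) and SPO20 (0.917) and high in ribosomal RNA (0.956), at 0.211% against 0.0316% to 0.0394%. Of the exponential libraries without metformin, the one numbered 3 was high in TRR1 (0.884) and low in COX1 (0.871) and YDR170W-A (0.979). The library numbered 2 was high in GRE1 (0.898) and PUT4 (0.855), and the library numbered 1 in AHA1 (0.853).

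The metformin effect differed between the phases by the interaction test for TRR1 (1.11) and, by camera with the preset correlation, for 14 lists. It was more positive in stationary cultures for heat shock chaperones (median 0.40), mitochondrially encoded oxidative phosphorylation (0.35), the retrograde response (0.28), oxidative stress defence (0.23), Ty genes (0.23), the tricarboxylic acid cycle (0.19), histones (0.16), mating genes (0.16), sulfur assimilation (0.13) and mitochondrial ribosomal proteins (0.080). It was more negative for hexose transporters (-0.42), meiosis and sporulation (-0.33), the iron regulon (-0.25) and ribosome biogenesis (-0.16). With an estimated correlation 0 of these lists passed, and by fry 0. Of 100 random splits 11 gave as many genes as the real 1, with 177 as the highest other, and 15 gave as many lists as the real 14, with 20 as the highest other. Among all 64 splits that part every pair within the phases, as the real one does, 11 gave 1 gene or more (highest other 6) and 12 gave 14 lists or more (highest other 21). Chance is therefore not excluded for either count, and the split with 177 genes points to a structure of the samples.

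TRR1 and GPX2 were higher with metformin in stationary cultures. Reads shared with paralogs would raise TRR2, GPX1 and HYR1 as well, and the highest of these stood at -0.036, which argues against it. A single library would take the rise with it, yet the lowest value without any library was 1.14 for GPX2 and 0.97 for TRR1, although the call of GPX2 ended without stat_control 1 or 2 or stat_metformin 1 or 3. Of the 10 splits of these 6 libraries 2 gave as many genes as the real 3, the highest other was 168, and 10 splits are too few for a share under 0.05. A response of TRR1 and GPX2 to oxidants under metformin may remain as a hypothesis, which measured peroxide or thioredoxin oxidation in the same cultures would test. Without metformin both genes stood higher in exponential than in stationary cultures. GPX2 had 54.5 to 72.0 against 9.41 to 16.2 CPM, and TRR1 275.3 to 308.4 against 34.7 to 39.4 CPM. Whether stationary cultures with metformin were less far along was not tested for these genes.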

How the results depend on the processing

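For metformin in exponential cultures the 6 genes became 0 with glmTreat and between 2 (without exp_control 1) and 5 (without exp_metformin 3) with a library left out. In stationary cultures the 3 genes became 10 with the replicate block, 47 with DESeq2, 7 with limma-voom, 0 with glmTreat and 0 in the fit of these groups alone, and between 1 and 13 with a library left out. For the interaction the 1 gene became 0 with the block, 0 with glmTreat, 15 with DESeq2, 2 with the stricter filter, and between 0 and 16 with a library left out. Without both exponential libraries numbered 3, an alternative chosen after seeing the data, it became 0 (TRR1 adjusted p = 0.0782). In exponential cultures that alternative ended the calls of ADY2 (0.78, adjusted p = 1.00), hexose transporters (0.077, 0.142), meiosis and sporulation (0.0045, 0.751), mannoproteins and seripauperins (0.054, 0.511), gluconeogenesis (0.065, 0.129), the proteasome (-0.034, 0.247) and cytosolic ribosomal proteins (-0.043, 0.0520).

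Of the 12, 12, 21 and 20 lists in the first 4 comparisons, 1, 0, 0 and 0 passed with an estimated correlation. By fry 0 passed in each metformin comparison and 34 for the phases with metformin, where fry tests no other genes. The 0 Ty families in stationary cultures with metformin became 3 with the replicate block, 2 with DESeq2 and between 0 and 2 with a library left out. The correlation of metformin and phase effects became 0.225 with the controls split (mean of 6 splits, 0.0322 to 0.392), where shared controls no longer add to it.

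The direction by camera reversed for heat shock chaperones in exponential cultures, which ranged from -0.32 to 0.044 with a library left out, and for cytosolic ribosomal proteins in stationary cultures, from -0.19 to 0.016. The median of gluconeogenesis genes in exponential cultures turned to -0.018 without exp_control 3, while camera kept the direction. The cause of these changes was not tested unless stated. Among single genes, lists and families, 2852 results kept their call or stayed without one under the planned settings, 195 lost their call and 16 gained one. Results without a call in either fit were counted as kept whatever their direction. With the replicate block 16, 15, 20 and 22 lists passed in the first 4 comparisons and 19 instead of 14 in the interaction. Among the named genes, the lists that passed without the block in the first 4 comparisons and the Ty families, the block changed no call other than those given here and in the report. The sums with long terminal repeats were not run, as the table has no such features.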

Other observations

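Several groups of genes moved apart within themselves between the phases without metformin, in lists that did not pass as a whole; the genes named in this paragraph were chosen after their values were seen. Of 18 hexose transporters 12 rose and 4 fell, also adjusted over the list alone: HXT5, a transporter of slow growth, stood at 7.55 (SE 0.59) and HXT1, a low-affinity transporter, at -4.27 (SE 0.17). Of 18 phosphate regulon genes 8 rose and 4 fell, from PHO84, a phosphate transporter, at 7.20 (SE 0.48) to GPP2, a glycerol phosphatase, at -2.70 (SE 0.14). Of 27 genes of sulfur assimilation and methionine 12 rose and 11 fell, from SUL1, a sulfate transporter, at 5.57 (SE 0.24) to CYS3, an enzyme of cysteine synthesis, at -5.64 (SE 0.15); both tallies were the same adjusted over the list alone. Of 22 mating genes of MATa cells 12 fell and 6 rose, also adjusted over the list alone, with the pheromone receptor STE2 at -3.12 (SE 0.11), the protease BAR1 at -2.74 (SE 0.13) and FUS2, a gene of cell fusion, at 3.18 (SE 0.19). Heat shock chaperones fell in 16 of 23 cases and rose in 2, over all genes and adjusted over the list alone.

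In the paragraphs that follow, the splits, the tests on iron members lower in stationary cultures, on the zinc and copper lists and on the lowest genes, and the use of the planned fits and scaling to weigh explanations, were chosen after the results were seen. Iron regulon genes were higher with metformin in exponential cultures, with a median of 0.29. Cultures further along toward stationary phase would lower the 10 members that are lower there. Yet 9 of these were higher, with a median of 0.35, and of the 6 that fell by the test 5 were higher, with a median of 0.22. The SE of the mean was 0.07 for the 10 and 0.08 for the 6. It was taken over genes, which share the same libraries and are not replicates, so it measures no spread between cultures. No single library carried the list, since its lowest median without any library was 0.24 (highest adjusted p = 1.38e-21), and 1 of 35 splits, the real one, gave so high a median (highest other 0.24), but only 8 part as many pairs (highest other 0.14), too few for a share under 0.05. A lower supply of metals in general would raise the zinc list as well, but its upper quartile was 0.047. The upper quartile of the copper list was 0.096, which decides nothing. That list mixes genes of copper uptake with genes of copper excess. A lower iron supply or iron use under metformin may explain the pattern, as a hypothesis that cellular iron and added iron would test, while a transitional state unlike late stationary phase stays open.

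Ty genes were higher with metformin in stationary cultures, with a median of 0.41. With library size and scaling from nuclear protein-coding genes, which leaves non-coding RNA out, the median was 0.41 and 44 genes were positive. That scaling moved the median of all genes only from 0.0131 to 0.0135. These values argue against scaling to libraries filled by non-coding RNA, and say nothing about other faults of the scaling. Genomic DNA would raise the 200 lowest genes by as many counts, but the upper quartile of their change was -0.0273 CPM against a median of 4.70 CPM for Ty genes. The lowest median without any library was 0.27 (adjusted p = 4.26e-07), and 2 of 10 splits gave as high a median (highest other 0.50), too few for a share under 0.05. Among the 4 splits that part as many pairs the highest other was 0.28, and these are too few as well. What lies behind the higher values stays open, since 0 families passed in the edgeR test without the block, and more cultures and unique-read counts would test it.

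Splits of the same libraries show what their grouping by chance can give. For metformin in exponential cultures 3 of 35 splits gave as many genes as the real 6, so chance is not excluded by this count. The highest other, 453, puts both libraries numbered 3 on the same side, which points to a structure of the samples, and among the 8 splits that part as many pairs the highest other was 0. For lists 17 of 35 splits reached the real 12 (highest other 19), so chance is not excluded. In stationary cultures 4 of 10 splits reached the real 12 lists (highest other 15), too few for a share under 0.05. There, too, a split with 168 genes points to a structure of the samples, and among the 4 splits that part as many pairs the highest other was 0.

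For the phases without metformin 1 of 35 splits, the real one, gave 2585 rising and 2574 falling genes (highest other 3810 in all), a share under 0.05. With metformin 1 of 35 splits, the real one, gave 5036 genes (highest other 3666). Only 8 of these splits part as many pairs (highest other 3390), too few for a share under 0.05. Splits that call so many genes point to the structure of the samples by phase. The counts of lists and Ty families decide nothing about chance, since with 4 against 3 libraries every split keeps part of the phase difference. For lists 9 of 35 splits without metformin were at the real 21 or above (highest other 24, median 18) and 12 of 35 with it at 20 or above (highest other 23, median 17). For the families, of which there are only 4, 3 of 35 and 5 of 35 splits reached the real 4 (highest other 4), while each family had an exact permutation p of 0.0286 in both comparisons.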
